A study of Homo sapiens with 71 samples.

How the data were processed

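RNA of differentiated HepaRG cells was hybridized to single-colour Cy3 arrays, and 71 arrays on 9 slides were deposited. Per the labels the cells were exposed to magnetic mesoporous silica nanoparticles with a Pristine, PEG or DMPC surface at 1.6, 16 or 80 µg/cm², to chlorpromazine at 100 µM, or to medium alone. Exposure lasted 24 or 48 h. The labels speak of separate cultures and of independent experiments as replicates. Groups and replicate numbers were taken from the labels, and the slide of each array from the slide number that the labels give.

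The arrays were scanned and read with Feature Extraction 11.0.1.1, as the file headers state. Per the file headers the processed signal used for every comparison is an intensity from which the background was subtracted and a spatial trend removed, 1 array at a time, with no normalization between arrays. The deposited scanner files also give the median pixel intensity of each spot and of its local background, which are raw. Per the file headers the other columns used are flags that mark a spot as a control, saturated, uneven or well above background. The deposited series table, although named normalized, holds an intensity for each spot that was equal to the raw median signal, with 0 differing values over all arrays, so its scale is that of the scanner and it was not centred. Its column medians lay between 21 and 51.

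Of 60901 spots per array that are not controls, those of 1 probe were averaged after taking log2, which left 58201 probes. Spots marked as uneven or as outliers, 53 to 182 per array, were left out. The log2 of the processed signal less the 75th percentile of its array was the level of a probe. Accessions of 31104 probes matched 22439 gene symbols of a reference on the current human assembly, and the 27097 probes without a match kept the name in the file. Of several probes for 1 gene name the probe with the highest mean level over all arrays was used, for 47753 names. Other probes of 14 genes named in the report, where well above background, gave 40 further values. Of these 0 had the opposite direction and 9 did not pass, among them those of CYP2B6 in 4 comparisons, where its other probe moved less, and of CENPF in 3. A gene was tested in a slide set when its probe was well above background on every array of at least 1 group of the set, which left 19691, 19912 and 17584 genes for the set at 24 h, the set at 48 h and the set with 80 µg/cm². A gene not well above background on any array of a group has a bound there, computed as the mean of the brighter group less the mean over the dim group's arrays of the higher of the dim probe's level and the lowest level among probes well above background.

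Depth is signal over background here. Probes well above background made up 31.0% to 45.9% of an array, and 0 gene probes were saturated on each array. The precision is given as the SE of each log2 change.

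Changes were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the package data.table, version 1.17.8, with group as the only term and 1 fit per slide set, so that all groups of a set share an estimate of the spread. Each exposure was compared with the control of its slide set and time, the 3 surfaces at 16 µg/cm² with limma's F test, and the surfaces at 80 µg/cm² in pairs. The interaction was the change at 48 h less that at 24 h, and the controls of both times were compared as well. Genes passed at a Benjamini-Hochberg adjusted p below 0.05. The array of DMPC at 1.6 µg/cm² and 24 h that lies on a slide without 24 h controls was left out of the fits and used only in an alternative. Every group of a set lay on each of its slides at 1 place that did not change, apart from 2 arrays placed apart, so place and group can be set against each other only through those 2 arrays. Each slide held 1 array per group, apart from a slide with 2 arrays of the 48 h control, so a change within a slide has no test of its own.

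The 28 gene lists held 585 genes, of which 565 were on the array. Lists with at least 5 tested members went through camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Members were also counted as adjusted over the list alone. Genes are named in the report by a fixed rule. For each comparison it takes the 10 most raised and 10 most lowered genes among those that passed and moved the same way on each slide, leaving out names of noncoding loci and clones, and up to 4 members per list with the lowest adjusted p. A gene named so in 1 comparison may be given in others. Symbols of snoRNAs and other short RNAs were taken from the biotypes of the reference.

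The alternatives were quantile normalization, normexp background correction with an offset of 50, no filter on dim probes, the replicate number, which is the slide, as a block, the deposited table, and leaving out arrays in turn. Normexp was run on the median signal and the median background, and a mean signal was not used here. Close pairs of arrays were averaged, and arrays nearest to another group were left out, as alternatives chosen after the data had been seen. A pair counted as close when its distance, the median absolute difference of levels, was at most 0.6 times that of either array to the rest of the group among the arrays compared. In DMPC at 1.6 µg/cm² and 24 h replicates 2 and 3 (0.116) counted so, with the array left out of the fits, at 0.136 and 0.0803 from them, not considered.

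The steps were tested on simulated arrays with the spread of each slide set, known changed genes and an unchanged comparison, in which limma recovered most changed genes. Shared controls were simulated 20 times. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.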

Results

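The series measured gene expression in differentiated HepaRG cells, an established human hepatic line whose cultures hold hepatocyte-like and biliary-like cells. The cells were exposed to magnetic mesoporous silica nanoparticles that carried no coating (Pristine) or a PEG or DMPC surface. The doses were 1.6, 16 and 80 µg/cm², the exposures lasted 24 or 48 h, and chlorpromazine at 100 µM for 24 h served as a toxic reference. Each group had 3 arrays, except the 48 h control of the lower doses and DMPC at 1.6 µg/cm² for 24 h, which had 4 each. The 71 arrays lay on 9 slides in 3 sets of 3. A first set held the lower doses at 24 h, another the lower doses at 48 h, and the last all arrays at 80 µg/cm² with their own controls at both times. Between 31.0% and 45.9% of the probes of an array were well above background, no gene probe was saturated, and the 75th percentile of the processed signal lay between 41.6 and 130.8. Signal moved with the groups: its mean was 98.5 in 24 h control cells of the first set, 105 with Pristine, 78.9 with PEG and 54.3 with DMPC at 16 µg/cm², the order in which the counts of changed genes rise. At 80 µg/cm² and 48 h it was 94.6 with DMPC against 45.0 in control cells. Genes passed at a Benjamini-Hochberg adjusted p below 0.05 in limma, and changes are log2 differences ± the standard error (SE) of limma's fit with n = 3 arrays per group unless another n is given. Gene lists fixed before the data were examined were tested with camera at a preset correlation, and a camera p given alone also passed, or missed, the threshold with an estimated correlation. A gene not well above background on any array of a group has only a lower bound for its change, written as at least N-fold, which holds for the probe used. Arrays within a group were not equally far apart: among those compared 12 pairs, in 11 groups, lay far closer to each other than to the rest of their group, so the SE measures the spread between these arrays, part of which may be technical.

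**Figure D1:**
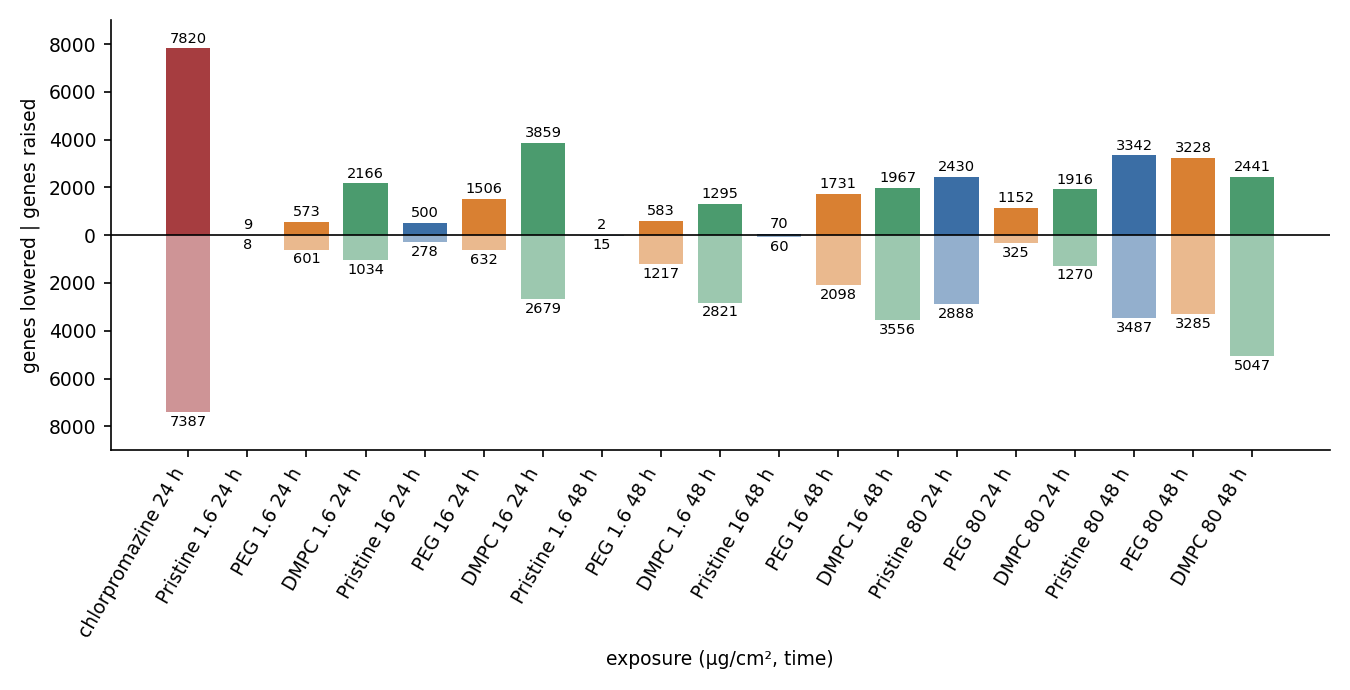
Genes that rose (upward bars) and fell (downward bars) against the control of the same slides and time, 1 bar pair per exposure, as counts of genes past the adjusted threshold. At 1.6 and 16 µg/cm² the count was lowest for Pristine at both times, with 17 genes at 1.6 µg/cm², and at 80 µg/cm² and 48 h the counts were 6829 for Pristine, 6513 for PEG and 7488 for DMPC.

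Chlorpromazine, the reference exposure, turned down much of the hepatocyte program and raised stress genes. HSPA6, a strictly heat-inducible HSP70 chaperone, rose by 8.45 ± 0.31, the matrix protease gene MMP1 by 7.75 ± 0.20, the stress-induced regulators ATF3 by 6.72 ± 0.07 (1 of its other probes 1.99) and DDIT3 by 6.10 ± 0.12, and the interleukin receptor gene IL1RL1 by 8.47 ± 0.12. The cytokine gene IL24 rose at least 405-fold by the probe used, and less by its other probe, and C11orf96 at least 789-fold. The drug-metabolizing enzyme CYP3A4 changed by -7.37 ± 0.09, and the sterol hydroxylase CYP8B1 of bile acid synthesis was at least 504-fold lower. Among phase I drug metabolism genes 0 of 23 rose and 23 fell (camera adjusted p = 1.73e-11), among phase II genes 1 of 17 rose and 16 fell (camera adjusted p = 1.31e-08), and among hepatocyte markers 0 of 30 rose and 29 fell (camera adjusted p = 7.08e-16). In the ATF4 and integrated stress response list 19 of 20 rose and 1 fell (camera adjusted p = 5.12e-07), and of ER chaperones 17 of 18 rose and 0 fell (camera adjusted p = 6.16e-06), with DNAJB9 at 3.66 ± 0.09 and HERPUD1 at 3.49 ± 0.09. Of NF-kB targets 14 of 18 rose and 4 fell (camera adjusted p = 4.24e-04, but 0.0816 with an estimated correlation), and of mitotic genes 1 of 25 rose and 24 fell (camera adjusted p = 1.71e-07, but 0.204 with an estimated correlation). The markers of blood, macrophage and endothelial cells went both ways, as 2 of 8 rose and 5 fell (camera adjusted p = 0.16), among them CD14, which changed by -4.30 ± 0.14. In all 15207 of 19691 genes changed, 7820 up and 7387 down. For chlorpromazine the count was 31655 with no filter on dim probes (76.2% raised against 51.4%).

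Pristine particles at the lower doses and 24 h were compared with control to see what the uncoated surface does. At 16 µg/cm² the muscle-type ubiquitin ligase gene TRIM63 rose by 3.71 ± 0.15, the metallothionein MT1F, which binds zinc, by 2.43 ± 0.13 and the chemokine gene CCL2 by 0.75 ± 0.06, while CYP3A4 changed by -1.41 ± 0.09 and CYP2A13 by -1.27 ± 0.10. The transferrin receptor gene TFRC, which brings iron into cells, changed by -0.76 ± 0.07. Of the phase I genes 0 of 23 rose and 11 fell (0 and 16 adjusted over the list alone, camera adjusted p = 1.14e-17), and of phase II genes 0 of 17 rose and 5 fell (0 and 8 adjusted over the list alone, camera adjusted p = 1.13e-08), with GSTA2 at -0.65 ± 0.08. Metallothioneins and zinc transporters went the other way, as 7 of 11 rose and 0 fell (camera adjusted p = 1.29e-14), and so did NF-kB targets, of which 7 of 18 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 2.57e-12). Bile acid genes fell in 8 of 27 (12 adjusted over the list alone, camera adjusted p = 5.07e-09) and hepatocyte markers in 5 of 30 (10 adjusted over the list alone, camera adjusted p = 2.52e-09). Lysosome genes rose in 5 of 29 (7 adjusted over the list alone, camera adjusted p = 4.77e-05) and cytoskeleton and SRF targets in 4 of 18 (camera adjusted p = 0.00718). At 1.6 µg/cm² the count was 17 genes, 9 up and 8 down, with CYP3A4 at -0.74 ± 0.09. Of the phase II list 0 of 17 rose and 0 fell (0 and 3 adjusted over the list alone, camera adjusted p = 9.52e-06), and the list as a whole lay below other genes with a median of -0.14. With 16 µg/cm² 778 genes changed, 500 up and 278 down. Pristine at 1.6 µg/cm² and 24 h gave counts of 14 with normexp background correction (35.7% raised against 52.9%), 7 with no filter on dim probes, 11 from the authors' deposited table (45.5% raised), 4 with close pairs of arrays averaged and 103 without the arrays nearest to another group (63.1% raised). Any 1 array left out gave 6 to 11 genes for Pristine at 1.6 µg/cm² and 24 h. The count for Pristine at 16 µg/cm² and 24 h was 372 with no filter on dim probes. It was 396 without control replicate 1 or 2 and 491 without control replicate 3.

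PEG-coated particles at 24 h shared the fall of CYP3A4, at -1.47 ± 0.09 for 16 µg/cm² and -0.56 ± 0.09 for 1.6 µg/cm². The higher dose raised TRIM63 by 3.30 ± 0.15, MT1X by 1.27 ± 0.13, CCL2 by 1.24 ± 0.06 and ICAM1, a leukocyte adhesion receptor, by 0.87 ± 0.07. Phase I genes fell as a group at that dose, since 0 of 23 rose and 13 fell (0 and 14 adjusted over the list alone, camera adjusted p = 8.38e-17), as did phase II genes, since 0 of 17 rose and 6 fell (1 and 8 adjusted over the list alone, camera adjusted p = 1.47e-06). NF-kB targets rose, with 9 of 18 (10 adjusted over the list alone, camera adjusted p = 8.62e-08) past the test, and so did 7 of 11 (8 adjusted over the list alone, camera adjusted p = 2.82e-07) metallothionein and zinc genes. In the DNA replication list 13 of 24 rose and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 1.71e-09, but 0.21 with an estimated correlation), with the helicase subunit MCM2 at 0.59 ± 0.10. Probes for small nucleolar RNAs (snoRNAs, guides for RNA modification) stood among the most lowered, with SNORA28 at -3.52 ± 0.17 and -3.11 ± 0.17 at the higher and lower dose, and 51 and 39 of 184 measured snoRNAs fell. The lower dose raised 6 of 11 (8 up and 1 down adjusted over the list alone, camera adjusted p = 0.00112, but 0.323 with an estimated correlation) metallothionein and zinc genes. The counts were 2138 genes (1506 up, 632 down) at 16 µg/cm² and 1174 (573 up, 601 down) at 1.6 µg/cm². For PEG at 1.6 µg/cm² and 24 h the count was 2501 with normexp background correction (56.8% raised against 48.8%), 3901 with no filter on dim probes (86.3% raised) and 985 from the authors' deposited table (57.7% raised). Any 1 array left out gave 482 to 682 genes for PEG at 1.6 µg/cm² and 24 h. PEG at 16 µg/cm² and 24 h gave counts of 1655 with quantile normalization (56.2% raised against 70.4%), 1268 with normexp background correction (51.6% raised), 857 with no filter on dim probes and 1101 from the authors' deposited table (60.4% raised). It was 974 without control replicate 1, 1220 without control replicate 2, 1339 without control replicate 3, 1017 without PEG replicate 2 and 1367 without PEG replicate 3.

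DMPC-coated particles at 24 h raised genes of amino acid stress, metal binding and DNA replication. The liver hormone gene FGF21 was at least 4.2-fold higher at 16 µg/cm² and at least 3.04-fold higher at 1.6 µg/cm². The asparagine synthetase gene ASNS rose by 1.14 ± 0.13 and 1.15 ± 0.13 in that order of doses, and CHAC1, which degrades glutathione, by 1.79 ± 0.18 and 1.54 ± 0.18. MT1F rose by 2.01 ± 0.13 at the higher dose, and HMOX1, which breaks down heme, by 0.91 ± 0.09. Down went ADH4 (-1.25 ± 0.13 and -0.93 ± 0.13). At 16 µg/cm² the replication list had 22 of 24 (camera adjusted p = 4.78e-12, but 0.173 with an estimated correlation) genes raised, the ATF4 list 13 of 20 (1 fell, camera adjusted p = 3.23e-04, but 0.139 with an estimated correlation) raised and the metallothionein list 8 of 11 (camera adjusted p = 2.47e-07, but 0.0623 with an estimated correlation) raised. NRF2 targets, which include oxidative stress enzymes, did likewise, as 11 of 19 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 0.00427, but 0.144 with an estimated correlation). Of phase II genes 1 of 17 rose and 6 fell (1 and 9 adjusted over the list alone, camera adjusted p = 7.06e-04), and of bile acid genes 0 of 27 rose and 17 fell (0 and 19 adjusted over the list alone, camera adjusted p = 4.58e-07, but 0.139 with an estimated correlation). At 1.6 µg/cm² 20 of 24 (22 adjusted over the list alone, camera adjusted p = 1.66e-12, but 0.144 with an estimated correlation) replication genes rose and phase II genes fell in 3 of 17 (camera adjusted p = 3.67e-04). The snoRNA SNORA28 changed by -3.03 ± 0.17 at 16 µg/cm², and 72 and 68 of 184 snoRNAs fell at the higher and lower dose. A set of noncoding and other probes, among them LINC02245 (3.37 ± 0.94), CASC15 (3.54 ± 0.84, its other probe 0.37) and CD86 (3.15 ± 0.87), headed the raised genes at both doses, but their level differed between arrays of the same group by up to 4.20, in Pristine at 16 µg/cm², on the log2 scale. DMPC changed 6538 genes at 16 µg/cm² (3859 up, 2679 down) and 3200 at 1.6 µg/cm² (2166 up, 1034 down). The count for DMPC at 1.6 µg/cm² and 24 h was 2819 with quantile normalization (52.3% raised against 67.7%), 7514 with normexp background correction and 14519 with no filter on dim probes (91.5% raised). It was 1676 without control replicate 1 and 1860 without control replicate 2. For DMPC at 16 µg/cm² and 24 h the count was 5944 with quantile normalization (48.9% raised against 59%), 10026 with normexp background correction and 19517 with no filter on dim probes (86.1% raised).

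The difference between surfaces was tested directly at 16 µg/cm² and 24 h with an F test over the 3 particles. CYP3A4 differed (adjusted p = 1.54e-07), with -1.41 ± 0.09 for Pristine, -1.47 ± 0.09 for PEG and -0.28 ± 0.09 for DMPC. The limma call of DMPC against control (adjusted p = 0.0185) ended without control replicate 3 (-0.23, adjusted p = 0.0847), DMPC replicate 1 (-0.27, adjusted p = 0.0502) or DMPC replicate 2 (-0.27, adjusted p = 0.0566). TRIM63 differed as well (adjusted p = 6.69e-06), at 3.71 ± 0.15, 3.30 ± 0.15 and 2.08 ± 0.15 in that order, and MT1F did too (adjusted p = 1.93e-05), at 2.43 ± 0.13, 1.07 ± 0.13 and 2.01 ± 0.13. ASNS (adjusted p = 0.00134) stood at 0.38 ± 0.13 for Pristine (0.52 without Pristine replicate 2, adjusted p = 0.0353) and 1.14 ± 0.13 for DMPC. SNORA28 (adjusted p = 5.54e-10) stood at 0.15 ± 0.17 for Pristine against -3.52 ± 0.17 for PEG. The muscle LIM protein gene CSRP3 (adjusted p = 0.994) and CYP7A1 (adjusted p = 0.235), which starts bile acid synthesis, did not pass. In all 4121 of 19691 genes differed among the particles. The 3 particles at 24 h gave counts of 9827 with normexp background correction, 17445 with no filter on dim probes and 2209 with close pairs of arrays averaged. It was 867 without replicate 2 and 1108 without replicate 3.

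Over 48 h Pristine particles again changed few genes. With 16 µg/cm² MT1F rose by 1.83 ± 0.12 and TRIM63 by 2.04 ± 0.28, while CYP3A4 changed by -1.31 ± 0.13, each against 4 control arrays. With close pairs of arrays averaged the calls for TRIM63 and CYP3A4 ended (adjusted p = 0.151 and 0.0984). Metallothionein and zinc genes rose in 7 of 11 (7 up and 1 down adjusted over the list alone, camera adjusted p = 4.54e-11, but 0.0798 with an estimated correlation), and phase I genes fell in 5 of 23 (11 adjusted over the list alone, camera adjusted p = 3.31e-12, but 0.0909 with an estimated correlation). Of the mitotic list 1 of 24 rose and 0 fell (23 and 0 adjusted over the list alone, camera adjusted p = 2.02e-18, but 0.134 with an estimated correlation), with a median of 0.71. The count was 130 genes, 70 up and 60 down. At 1.6 µg/cm² 17 genes passed, 2 up and 15 down, among them C16orf82, at least 1.5-fold higher, and TELO2, which stabilizes large kinases, at -0.36 ± 0.06. Of log2 changes of 1.43 for C16orf82 and -0.36 for TELO2 normexp left 0.06 and -0.18 (adjusted p = 0.817 and 0.579). In the authors' table they were 0.25 and -0.27 (adjusted p over 0.5). Quantile normalization (adjusted p = 0.236 and 0.0564), no filter and close pairs averaged ended both calls too, and the replicate number as a block that of C16orf82. Leaving out any 1 array ended the C16orf82 call (adjusted p 0.0506 to 0.286), and any 1 but Pristine replicate 3 that of TELO2 (0.0709 to 0.134). No list passed there. The count for Pristine at 1.6 µg/cm² and 48 h was 3 with quantile normalization, 4 with normexp background correction, 21 with no filter on dim probes (76.2% raised against 11.8%), 6 from the authors' deposited table and 0 with close pairs of arrays averaged. Any 1 array left out gave 2 to 10 genes for Pristine at 1.6 µg/cm² and 48 h. For Pristine at 16 µg/cm² and 48 h the count was 174 with normexp background correction (78.7% raised against 53.8%), 20 with no filter on dim probes (80% raised), 95 from the authors' deposited table (65.3% raised), 1 with close pairs of arrays averaged and 47 without the arrays nearest to another group (66% raised). It was 37 without control replicate 1 (64.9% raised), 93 without control replicate 2 (65.6% raised), 64 without control replicate 3 (65.6% raised), 19 without Pristine replicate 1, 220 without Pristine replicate 2 (64.5% raised), 49 without Pristine replicate 3 and 38 without control replicate 4 (76.3% raised).

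With PEG at 48 h cell division genes stood above control, by a rise or a smaller decline over time. At 16 µg/cm² the kinetochore protein gene CENPF rose by 1.79 ± 0.19 (other probe 1.74, adjusted p = 0.134), PTTG1, which guards sister chromatid separation, by 1.54 ± 0.16, and the transcription factor gene E2F1 by 1.63 ± 0.16. Of mitotic genes 23 of 24 rose and 0 fell (23 and 1 adjusted over the list alone, camera adjusted p = 4.67e-26, but 0.0878 with an estimated correlation), and of replication genes 23 of 23 rose and 0 fell (camera adjusted p = 3.55e-25, but 0.0878 with an estimated correlation). CYP1A1, the classic target of the aryl hydrocarbon receptor (AHR), rose by 2.69 ± 0.51. CYP3A4 changed by -1.46 ± 0.13 and ADH4 by -1.01 ± 0.10. With close pairs of arrays averaged the CYP1A1 call ended (adjusted p = 0.0581), as it did with DMPC at 1.6 µg/cm² (adjusted p = 0.118). Hepatocyte markers fell in 19 of 30 (20 adjusted over the list alone, camera adjusted p = 5.15e-13, but 0.0878 with an estimated correlation), phase I genes in 17 of 23 (1 rose, 20 down and 1 up adjusted over the list alone, camera adjusted p = 1.45e-11, but 0.0878 with an estimated correlation) and acute phase genes in 10 of 20 (13 adjusted over the list alone, camera adjusted p = 2.37e-05, but 0.159 with an estimated correlation). Hypoxia and glycolysis genes rose in 12 of 20 (16 up and 2 down adjusted over the list alone, camera adjusted p = 5.03e-06, but 0.223 with an estimated correlation). At 1.6 µg/cm² mitotic genes rose in 20 of 24 (22 adjusted over the list alone, camera adjusted p = 4.83e-20, but 0.331 with an estimated correlation), with CENPF at 1.14 ± 0.19 (other probe 0.79, adjusted p = 0.565, the probe used adjusted p = 0.129 with close pairs averaged). The unstable probe set was among the most raised, with LINC02245 at 3.76 ± 0.76 and 2.84 ± 0.76 at the lower and higher dose, calls that ended with close pairs averaged (adjusted p = 0.225 and 0.212), the latter also without PEG replicate 2 or 3 (2.53 and 2.51, adjusted p = 0.0718 and 0.0714). 3829 genes changed at 16 µg/cm² (1731 up, 2098 down) and 1800 at 1.6 µg/cm² (583 up, 1217 down). PEG at 1.6 µg/cm² and 48 h gave counts of 1845 with quantile normalization (43.8% raised against 32.4%), 2732 with normexp background correction (19.3% raised), 385 with no filter on dim probes, 1 with close pairs of arrays averaged and 4384 without the arrays nearest to another group. It was 983 without control replicate 1, 864 without control replicate 4, 687 without PEG replicate 1 or 3 and 3084 without PEG replicate 2. The count for PEG at 16 µg/cm² and 48 h was 4063 with quantile normalization (52% raised against 45.2%), 3627 with normexp background correction (57% raised), 2019 with no filter on dim probes and 703 with close pairs of arrays averaged (55.8% raised). It was 2364 and 2452 without PEG replicate 2 and 3.

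Mitotic genes stood above the same control cells with DMPC-coated particles at 48 h too. CENPF was at 1.61 ± 0.19 for 1.6 µg/cm² (other probe 1.81, adjusted p = 0.11) and 1.41 ± 0.19 for 16 µg/cm². MT1F rose by 2.06 ± 0.12 at the higher dose, and CYP1A1 by 2.42 ± 0.51 at the lower one. The CYP2A7 and CYP2A13 enzymes changed by -1.87 ± 0.18 and -1.94 ± 0.15 at 16 µg/cm², CYP3A4 by -1.07 ± 0.13, the bile acid regulator NR0B2 by -1.17 ± 0.17 and the iron regulator HJV by -1.15 ± 0.14. Mitotic genes rose in 22 of 24 (23 adjusted over the list alone, camera adjusted p = 1.47e-24, but 0.175 with an estimated correlation) at the lower dose and 20 of 24 (21 adjusted over the list alone, camera adjusted p = 2.55e-12, but 0.282 with an estimated correlation) at the higher. At 16 µg/cm² 16 of 23 (17 adjusted over the list alone, camera adjusted p = 3.56e-07, but 0.282 with an estimated correlation) phase I genes fell, and 8 of 11 (camera adjusted p = 1.66e-10, but 0.0718 with an estimated correlation) metallothionein and zinc genes rose. At 1.6 µg/cm² the hepatocyte markers fell in 18 of 30 (21 adjusted over the list alone, camera adjusted p = 1.99e-07, but 0.175 with an estimated correlation), and of AHR targets 2 of 5 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.00377, but 0.175 with an estimated correlation). LINC02245 and CD86 of the unstable set rose by 4.17 ± 0.76 and 3.98 ± 0.73 at 16 µg/cm². The counts were 5523 genes at 16 µg/cm² (1967 up, 3556 down) and 4116 at 1.6 µg/cm² (1295 up, 2821 down). For DMPC at 1.6 µg/cm² and 48 h the count was 3987 with quantile normalization (47% raised against 31.5%), 1835 with no filter on dim probes, 2595 from the authors' deposited table, 185 with close pairs of arrays averaged and 6388 without the arrays nearest to another group. It was 2346 without DMPC replicate 1 and 2171 without DMPC replicate 2. DMPC at 16 µg/cm² and 48 h gave counts of 5830 with quantile normalization (45.9% raised against 35.6%), 3312 with no filter on dim probes and 1412 with close pairs of arrays averaged.

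**Figure D2:**
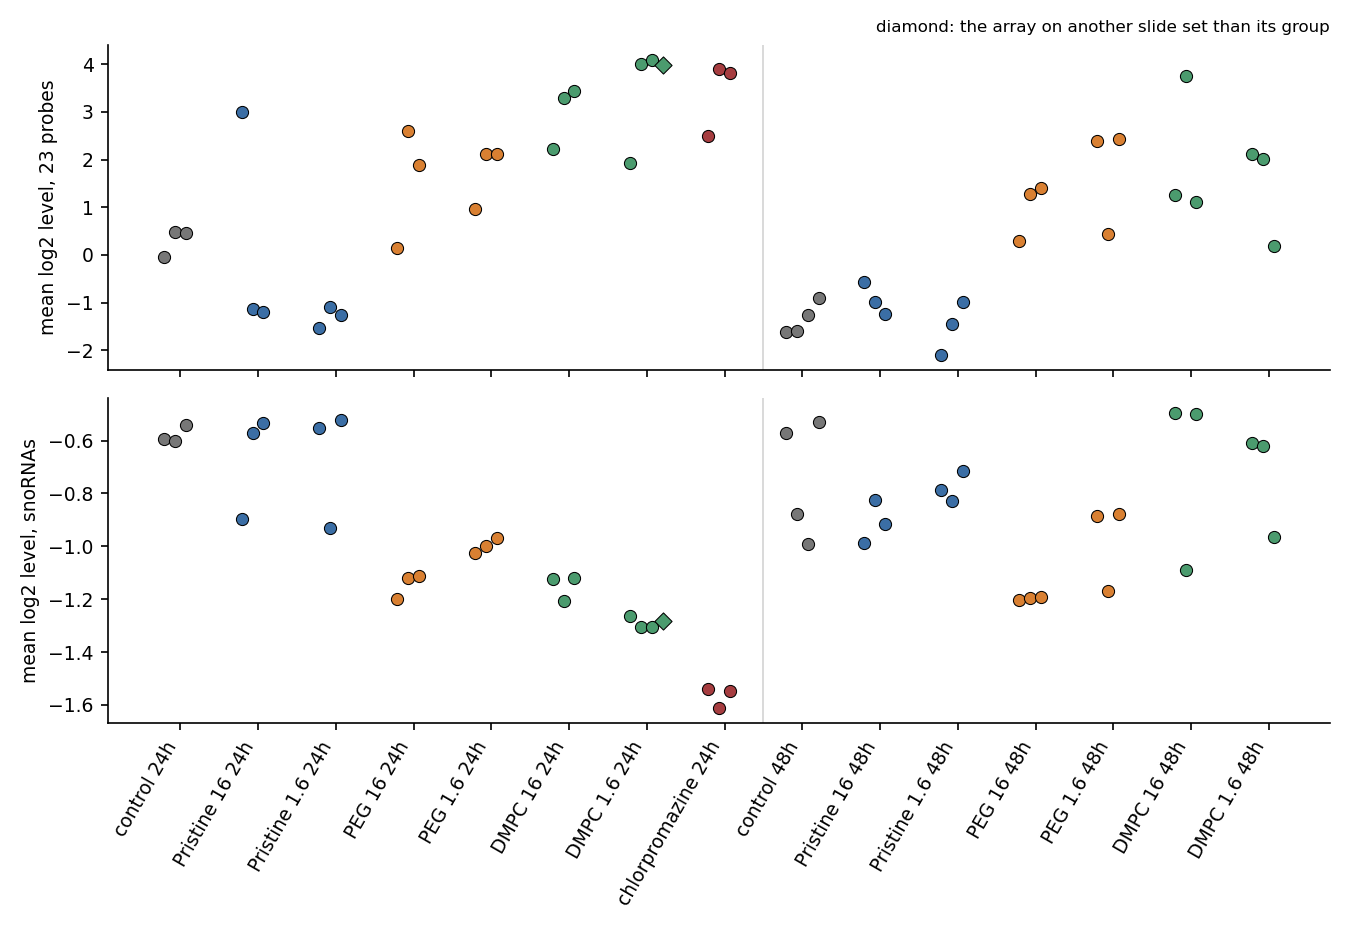
Mean log2 level over 23 probes that rose together (upper panel) and over all measured snoRNAs (lower panel), 1 point per array at 1.6 and 16 µg/cm² and in the controls of the same slides, on the scale of the array's 75th percentile. In DMPC at 1.6 µg/cm² and 24 h the 4 arrays stood at 1.92 and at 3.97 to 4.10 in the upper panel.

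At 16 µg/cm² and 48 h the F test over the 3 particles again found surface differences. MT1F differed (adjusted p = 3.38e-04), at 1.83 ± 0.12 for Pristine, 0.84 ± 0.12 for PEG and 2.06 ± 0.12 for DMPC. The mitotic cyclin gene CCNB1 differed (adjusted p = 0.00589), at 0.79 ± 0.22, 1.83 ± 0.22 and 0.83 ± 0.22 in that order (the last 0.57 without DMPC replicate 2, adjusted p = 0.0728), and CYP2A13 did (adjusted p = 0.00576), at -1.12 ± 0.15, -1.63 ± 0.15 and -1.94 ± 0.15. TRIM63 (adjusted p = 0.0054) stood at 2.04 ± 0.28, 2.93 ± 0.28 and 1.44 ± 0.28. CYP3A4 did not pass (adjusted p = 0.095). 6040 of 19912 genes differed among the particles. The count for the 3 particles at 48 h was 13622 with normexp background correction, 14851 with no filter on dim probes and 54 with close pairs of arrays averaged. It was 1946 without replicate 1 and 974 without replicate 3.

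At 80 µg/cm² and 24 h Pristine particles raised chaperone and cytokine genes and lowered liver enzymes. HSPA6 was at least 80.4-fold higher (log2 5.37 for its other probe) and the cytokine gene IL6 at least 52-fold higher, while CCL2 rose by 5.12 ± 0.16 and the cytokine brake SOCS1 by 4.61 ± 0.20. CYP7A1 was at least 30.4-fold lower, CYP3A4 changed by -3.70 ± 0.25, the glycine conjugation enzyme gene GLYAT by -3.22 ± 0.14 and G6PC1, the last step of glucose release, by -3.15 ± 0.28. All 16 of 16 (camera adjusted p = 2.21e-19) NF-kB targets rose. Phase I genes fell in 19 of 22 (20 adjusted over the list alone, camera adjusted p = 9.63e-19) and bile acid genes in 16 of 24 (17 adjusted over the list alone, camera adjusted p = 5.03e-11). Heat shock genes rose in 10 of 17 (11 adjusted over the list alone, camera adjusted p = 1.50e-08, but 0.173 with an estimated correlation), with HSPA1A at 2.73 ± 0.14, and of ATF4 targets 12 of 18 rose and 0 fell (13 and 1 adjusted over the list alone, camera adjusted p = 4.32e-09, but 0.173 with an estimated correlation). The biliary and progenitor markers went mostly up, as 6 of 11 rose and 2 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.00958, but 0.311 with an estimated correlation), with CD44 at 1.42 ± 0.18. The p53 target GDF15, a stress hormone, rose by 3.25 ± 0.14, and of its list 8 of 21 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.0113, but 0.569 with an estimated correlation). Of 17584 genes 5318 changed, 2430 up and 2888 down. For Pristine at 80 µg/cm² and 24 h the count was 6953 with no filter on dim probes (66.7% raised against 45.7%). It was 4832 without Pristine replicate 3 (53.5% raised).

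PEG-coated particles at 80 µg/cm² and 24 h raised TRIM63 by 4.67 ± 0.39, CCL2 by 2.56 ± 0.16 and GDF15 by 2.32 ± 0.14, and HSPA6 at least 6.07-fold (log2 1.82 for its other probe). TFRC changed by -2.29 ± 0.16 and the iron hormone gene HAMP by -1.89 ± 0.31, both genes of iron balance. NF-kB targets rose in 11 of 16 (16 adjusted over the list alone, camera adjusted p = 1.97e-18, but 0.11 with an estimated correlation), and phase I genes fell in 7 of 22 (11 adjusted over the list alone, camera adjusted p = 5.77e-10, but 0.125 with an estimated correlation). Lysosome genes rose in 9 of 28 (11 adjusted over the list alone, camera adjusted p = 8.00e-06, but 0.424 with an estimated correlation), with the cholesterol carrier NPC1 at 1.40 ± 0.19 and GPNMB at 1.56 ± 0.20. Replication genes rose in 13 of 23 (18 adjusted over the list alone, camera adjusted p = 8.26e-17, but 0.125 with an estimated correlation). 1477 genes changed, 1152 up and 325 down. PEG at 80 µg/cm² and 24 h gave counts of 2553 with quantile normalization (66.1% raised against 78%), 643 with no filter on dim probes and 685 with close pairs of arrays averaged. It was 768 without control replicate 2, 798 without control replicate 3, 776 without PEG replicate 1, 825 without PEG replicate 2 and 910 without PEG replicate 3.

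DMPC-coated particles at 80 µg/cm² and 24 h raised CCL2 by 3.72 ± 0.16, the chemokine gene CCL20 by 3.23 ± 0.17 and MT1X by 2.16 ± 0.14, with HSPA6 at least 14.1-fold higher (log2 3.29 for its other probe). CYP7A1 changed by -4.51 ± 0.70, G6PC1 by -2.88 ± 0.28 and CYP2A7 by -2.65 ± 0.30. Phase I genes fell in 18 of 22 (19 adjusted over the list alone, camera adjusted p = 2.14e-24) and bile acid genes in 14 of 24 (15 adjusted over the list alone, camera adjusted p = 6.66e-13). NF-kB targets rose in 15 of 16 (16 adjusted over the list alone, camera adjusted p = 1.68e-20), and metallothionein and zinc genes in 7 of 11 (camera adjusted p = 6.12e-10). Cytoskeleton and SRF targets rose in 11 of 17 (13 adjusted over the list alone, camera adjusted p = 7.05e-10, but 0.134 with an estimated correlation), with the tropomyosin TPM4 at 1.36 ± 0.11. Of the fibroblast and matrix markers 5 of 13 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.00439, but 0.445 with an estimated correlation). 3186 genes changed, 1916 up and 1270 down. The count for DMPC at 80 µg/cm² and 24 h was 1973 with no filter on dim probes and 1755 with close pairs of arrays averaged.

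The 3 particles at 80 µg/cm² and 24 h shared 1 control group, and their calls overlapped. All 3 raised 877 genes, where independent lists would share 17.4, and all 3 lowered 262, where such lists would share 3.86. The correlation of log2 changes across genes, which are not independent replicates, was 0.815 for Pristine with DMPC (covariance 0.258), against 0.5 (covariance 0.0368) for simulated unchanged groups with the same controls. It was 0.678 for Pristine with PEG (covariance 0.169, simulated correlation 0.499) and 0.804 for PEG with DMPC (covariance 0.159). The 3 controls could not be split, so part of the excess may come from them, and the simulated groups shared 0 calls in limma.

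Direct tests at 80 µg/cm² and 24 h set the surfaces apart. Against Pristine, PEG left higher CYP3A4 (by 3.05 ± 0.25), GLYAT (by 2.55 ± 0.14) and the fatty acid oxidation enzyme ACADL (by 2.01 ± 0.21). It left lower HSPA6 (-3.73 ± 0.28), IL6 (-3.03 ± 0.19) and CCL2 (-2.56 ± 0.16). Phase I genes were higher with PEG in 15 of 22 (19 adjusted over the list alone, camera adjusted p = 7.53e-20) and NF-kB targets lower in 11 of 16 (14 adjusted over the list alone, camera adjusted p = 3.09e-17, but 0.068 with an estimated correlation). DMPC against Pristine gave lower HSPA6 (-2.52 ± 0.28) and CHAC1 (-1.65 ± 0.18; other probe -0.85, adjusted p = 0.366), and higher mitotic genes in 11 of 23 (21 adjusted over the list alone, camera adjusted p = 1.20e-15, but 0.177 with an estimated correlation). DMPC against PEG gave lower CYP2B6 (-1.42 ± 0.13; other probe -0.82, adjusted p = 0.582) and higher MT1F (1.41 ± 0.17). There phase I genes were lower in 15 of 22 (17 adjusted over the list alone, camera adjusted p = 4.58e-33) and metallothionein and zinc genes higher in 6 of 11 (7 adjusted over the list alone, camera adjusted p = 1.08e-15). The counts were 2462 genes for PEG against Pristine (1807 higher, 655 lower), 728 for DMPC against Pristine (557 and 171) and 399 for DMPC against PEG (127 and 272). For PEG against Pristine at 24 h the count was 4175 with quantile normalization and 6278 with no filter on dim probes (24.6% higher against 73.4%). It was 1629 without PEG replicate 2. DMPC against Pristine at 24 h gave counts of 1838 with quantile normalization (64.9% higher against 76.5%), 1713 with normexp background correction, 3429 with no filter on dim probes (16.9% higher), 1530 from the authors' deposited table (86.9% higher) and 340 with close pairs of arrays averaged. It was 428, 394 and 392 without DMPC replicate 1, 2 and 3. The count for DMPC against PEG at 24 h was 1012 with quantile normalization, 193 with no filter on dim probes and 199 with close pairs of arrays averaged. It was 231 without PEG replicate 1, 235 without PEG replicate 2, 203 without PEG replicate 3, 245 without DMPC replicate 1 and 225 without DMPC replicate 2.

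**Figure D3:**
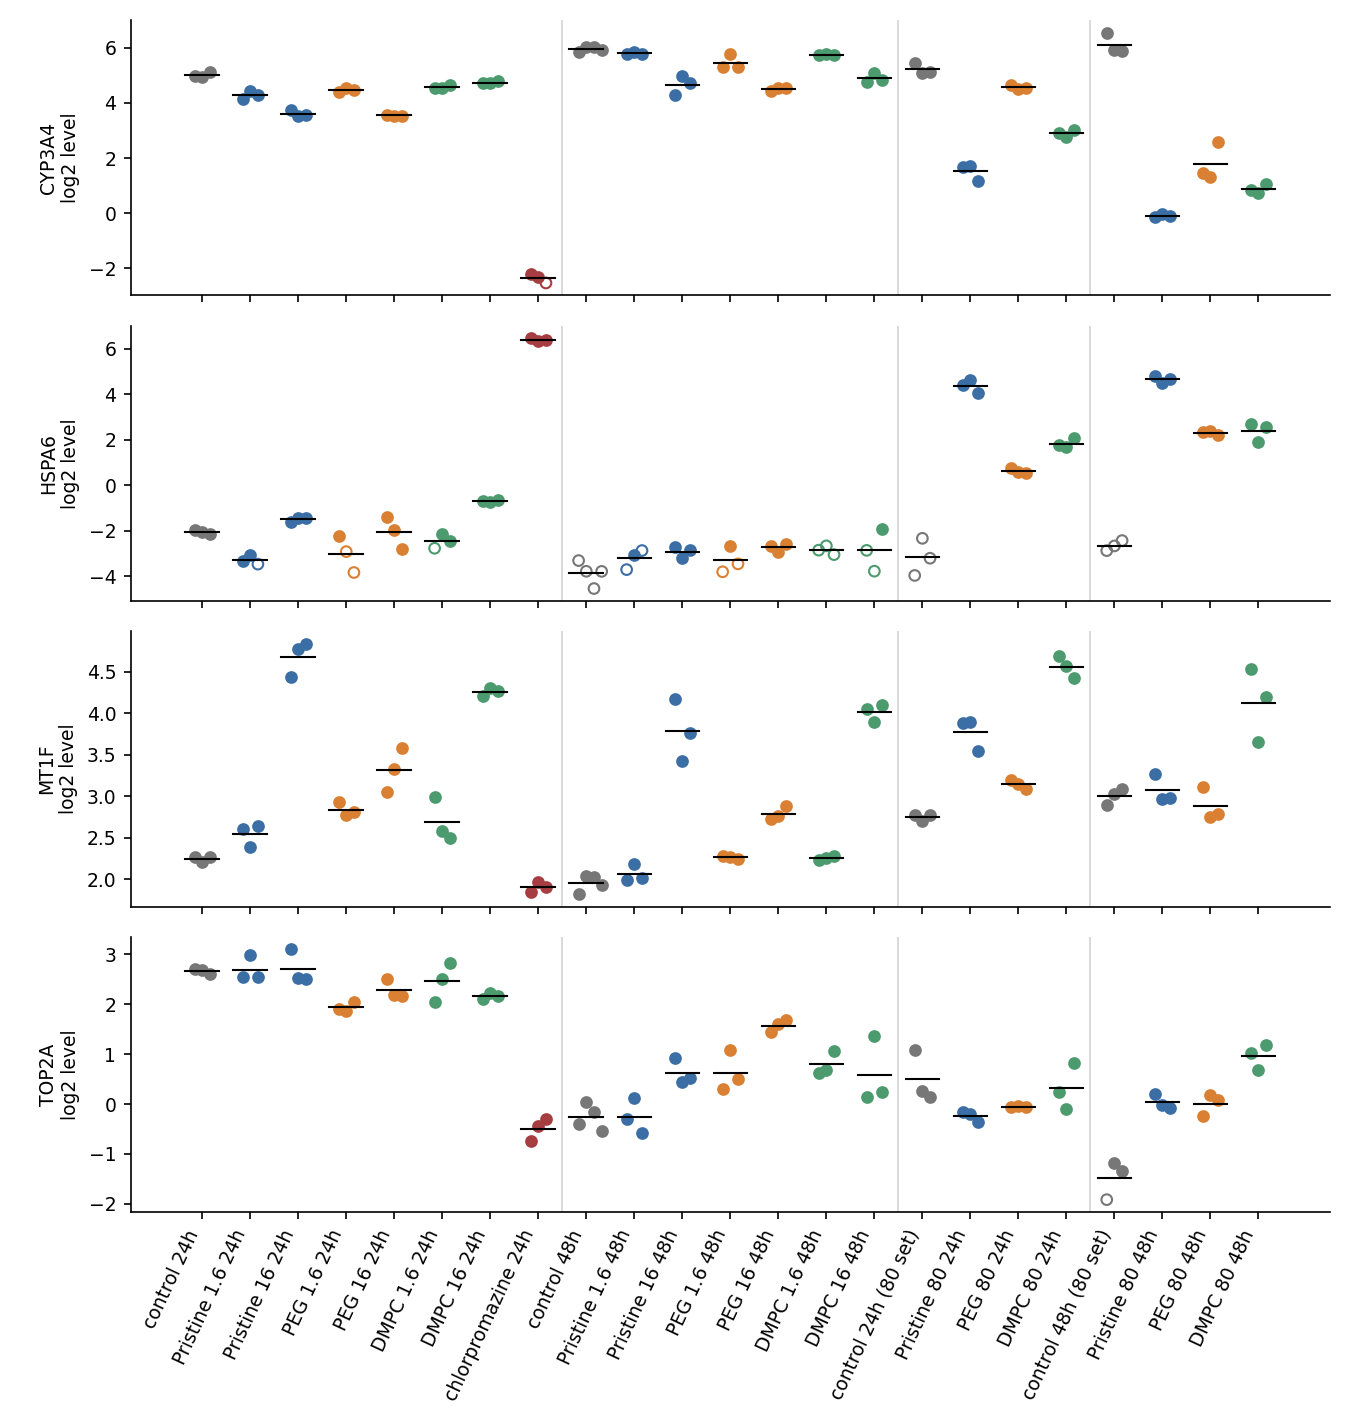
Log2 level of CYP3A4, HSPA6, MT1F and TOP2A on each array, relative to the array's 75th percentile, by group, with open symbols where the probe was not well above background and bars at group means. On every array with 80 µg/cm² CYP3A4 lay below each control array of the same time.

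At 48 h and 80 µg/cm² Pristine particles lowered liver enzymes, and division genes stood above control. CYP3A4 changed by -6.20 ± 0.25, CYP2B6 by -5.31 ± 0.13 (other probe -1.62), and the urea cycle genes CPS1 and ARG1 by -4.39 ± 0.13 and -4.16 ± 0.14. HSPA6 was at least 101-fold higher (log2 6.24 for its other probe), and the acute phase protein gene CRP rose by 3.63 ± 0.22. Phase I genes fell in 20 of 22 (22 adjusted over the list alone, camera adjusted p = 5.93e-20) and bile acid genes in 18 of 24 (camera adjusted p = 1.01e-12). Mitotic genes rose in 23 of 23 (camera adjusted p = 5.93e-20, but 0.0541 with an estimated correlation), with CDK1, the mitotic kinase, at 1.96 ± 0.13, against controls whose mitotic genes had fallen since 24 h. Cholesterol synthesis genes fell in 22 of 26 (23 adjusted over the list alone, camera adjusted p = 2.52e-11, but 0.132 with an estimated correlation), with HMGCS1 at -1.58 ± 0.16, and ATF4 targets rose in 17 of 18 (1 fell, camera adjusted p = 1.96e-13, but 0.0662 with an estimated correlation). Of interferon response genes 13 of 22 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 2.16e-04, but 0.219 with an estimated correlation), with OAS3 at 2.07 ± 0.22. 6829 genes changed, 3342 up and 3487 down. For Pristine at 80 µg/cm² and 48 h the count was 6218 with normexp background correction (54.1% raised against 48.9%).

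PEG-coated particles at 80 µg/cm² and 48 h lowered CYP3A4 (-4.33 ± 0.25), CYP7A1 (-5.70 ± 0.70) and CPS1 (-3.03 ± 0.13). TRIM63 rose by 5.63 ± 0.39, NPC1 by 2.39 ± 0.19 and the cystine carrier SLC7A11 by 2.86 ± 0.18. Phase I genes fell in 21 of 22 (22 adjusted over the list alone, camera adjusted p = 1.05e-17, but 0.0613 with an estimated correlation) and mitotic genes rose in 23 of 23 (camera adjusted p = 3.01e-16, but 0.0785 with an estimated correlation). Of NF-kB targets 16 of 16 rose and 0 fell (camera adjusted p = 4.28e-13, but 0.0785 with an estimated correlation), of ATF4 targets 15 of 18 rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 2.21e-14, but 0.0785 with an estimated correlation) and of cytoskeleton and SRF targets 14 of 17 rose and 1 fell (camera adjusted p = 1.01e-08, but 0.164 with an estimated correlation). Fatty acid and triglyceride synthesis genes fell in 15 of 18 (camera adjusted p = 5.29e-06, but 0.23 with an estimated correlation), with FASN at -1.51 ± 0.14. Of 152 snoRNAs 67 fell, as did 14 of 35 other short RNAs. 6513 genes changed, 3228 up and 3285 down. PEG at 80 µg/cm² and 48 h gave counts of 7284 with normexp background correction (58.3% raised against 49.6%) and 6052 from the authors' deposited table (55.8% raised).

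DMPC-coated particles at 80 µg/cm² and 48 h lowered ARG1 (-4.99 ± 0.14), CYP2B6 (-4.78 ± 0.13, other probe -2.17), CYP3A4 (-5.23 ± 0.25) and the bile acid ligase gene SLC27A5 (-4.36 ± 0.14). CENPF rose by 2.30 ± 0.15, E2F1 by 2.33 ± 0.16 and CCL2 by 2.80 ± 0.16. Phase I genes fell in 22 of 22 (camera adjusted p = 4.74e-20), hepatocyte markers in 25 of 28 (26 adjusted over the list alone, camera adjusted p = 1.54e-16) and bile acid genes in 21 of 24 (camera adjusted p = 4.99e-12). Mitotic genes rose in 23 of 23 (camera adjusted p = 1.31e-29) and replication genes in 23 of 23 (camera adjusted p = 5.50e-24). Of 152 snoRNAs 120 fell, with a median change of -1.40, as did 25 of 35 other short RNAs, with a median of -1.02. The median of all genes lay at -0.16 here, which was -0.05 with quantile normalization, -0.02 with normexp background correction and -0.03 without DMPC replicate 2. 7488 genes changed, 2441 up and 5047 down. The count for DMPC at 80 µg/cm² and 48 h was 7790 with quantile normalization (47.6% raised against 32.6%) and 11402 with normexp background correction (47.9% raised). It was 7146 without DMPC replicate 2 (53.6% raised).

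**Figure D4:**
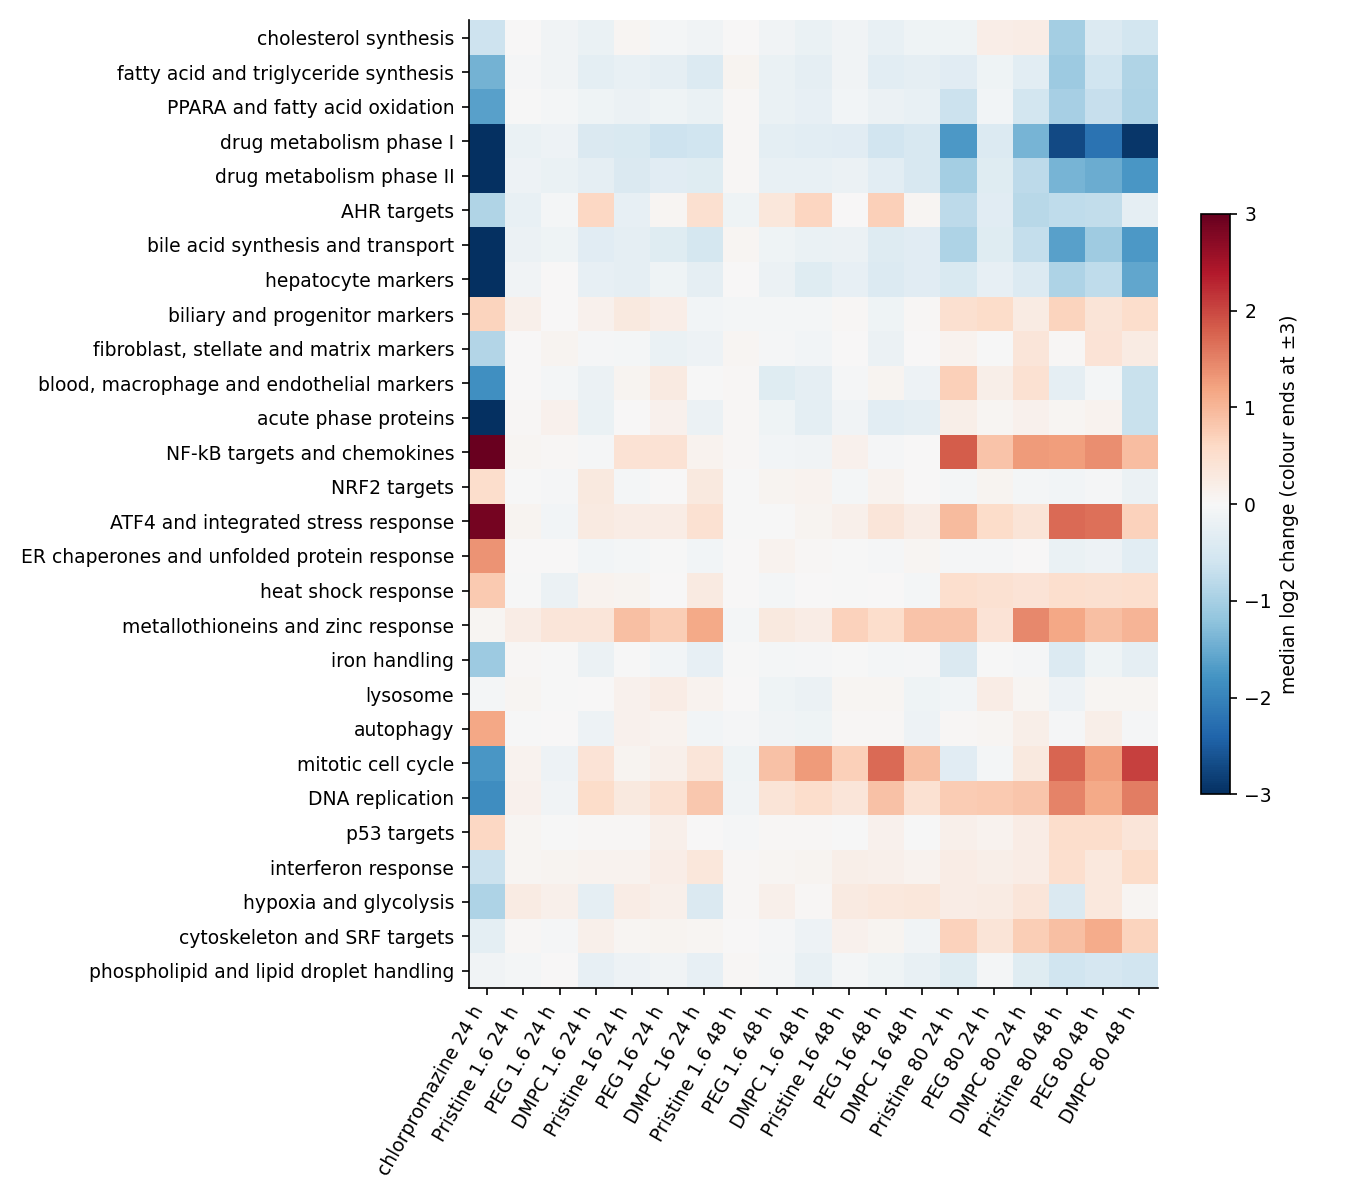
Median log2 change of the measured genes of each of the 28 lists in the 19 comparisons with control, as colour. The drug metabolism and bile acid lists lay below 0 in every 80 µg/cm² column and the NF-kB and metallothionein lists above 0.

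Calls at 80 µg/cm² and 48 h overlapped as well. All 3 particles raised 1735 genes, where independent lists would share 85.2, and all 3 lowered 2203, where such lists would share 187. Across genes the correlation was 0.872 for Pristine with PEG (covariance 0.488), against 0.497 (covariance 0.0366) for simulated unchanged groups, 0.783 for Pristine with DMPC and 0.842 for PEG with DMPC. As at 24 h, part of the excess may come from the 3 shared controls.

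Direct tests at 48 h found higher G6PC1, at least 2.99-fold, higher CYP2B6 (by 2.40 ± 0.13; other probe 0.13, adjusted p = 0.922) and higher CD36, a fatty acid carrier (by 3.30 ± 0.54), with PEG than with Pristine. HSPA6 was lower (-2.34 ± 0.28). Cholesterol synthesis genes were higher with PEG in 17 of 26 (22 up and 1 down adjusted over the list alone, camera adjusted p = 1.44e-20, but 0.0997 with an estimated correlation), and hypoxia and glycolysis genes in 12 of 20 (17 adjusted over the list alone, camera adjusted p = 4.57e-23, but 0.0997 with an estimated correlation), with NDRG1 at 1.62 ± 0.15. DMPC against Pristine gave lower ASNS (-1.72 ± 0.15) and APOA2, a lipoprotein gene (-1.27 ± 0.16), and acute phase genes lower in 16 of 20 (camera adjusted p = 5.49e-09, but 0.277 with an estimated correlation). DMPC against PEG gave lower ARG1 (-2.60 ± 0.14) and FABP1 (-1.73 ± 0.13), a fatty acid carrier of hepatocytes. Mitotic genes were higher there in 21 of 23 (camera adjusted p = 6.36e-30) and hepatocyte markers lower in 21 of 28 (23 adjusted over the list alone, camera adjusted p = 2.00e-17, but 0.0941 with an estimated correlation). The counts were 885 genes for PEG against Pristine (629 higher, 256 lower), 3311 for DMPC against Pristine (952 and 2359) and 1952 for DMPC against PEG (421 and 1531). For PEG against Pristine at 48 h the count was 1753 with quantile normalization, 1274 with normexp background correction (85.6% higher against 71.1%), 412 with no filter on dim probes and 716 from the authors' deposited table (82.1% higher). It was 576 without PEG replicate 1, 536 without PEG replicate 2, 562 without PEG replicate 3, 520 without Pristine replicate 2 and 449 without Pristine replicate 3. DMPC against Pristine at 48 h gave counts of 3927 with quantile normalization (47.5% higher against 28.8%), 8006 with normexp background correction (44.5% higher), 1691 with no filter on dim probes and 5452 from the authors' deposited table. It was 1939 without Pristine replicate 2, 1943 without Pristine replicate 3, 3761 without DMPC replicate 1 (18.5% higher) and 3066 without DMPC replicate 2 (61.6% higher). The count for DMPC against PEG at 48 h was 2488 with quantile normalization (41.8% higher against 21.6%), 3905 with normexp background correction (35.1% higher) and 963 with no filter on dim probes. It was 1130 without PEG replicate 1 and 1911 without DMPC replicate 2 (54.6% higher).

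Whether the response at 80 µg/cm² differed between 48 and 24 h was tested as an interaction. Mitotic genes moved up more at 48 h with Pristine in 22 of 23 (23 adjusted over the list alone, camera adjusted p = 4.58e-51), with a median of 2.11 and CENPF at 2.28 ± 0.21, in controls whose own mitotic genes fell over the same hours. CYP2B6 moved down more (-3.93 ± 0.18; other probe -0.13, adjusted p = 0.951), as did CPS1 (-2.05 ± 0.18), and the serine synthesis gene PHGDH moved up (2.28 ± 0.21). With PEG the mitotic median was 1.35 (camera adjusted p = 2.93e-32), and CYP3A4 moved by -3.68 ± 0.35. Phase I genes went down more in 15 of 22 (16 adjusted over the list alone, camera adjusted p = 1.88e-21), and ATF4 targets went up more in 13 of 18 (15 adjusted over the list alone, camera adjusted p = 9.75e-19). With DMPC the mitotic median was 1.78 (camera adjusted p = 2.85e-56), ARG1 moved by -3.06 ± 0.20 and FABP1 by -2.04 ± 0.19, and hepatocyte markers went down more in 21 of 28 (22 adjusted over the list alone, camera adjusted p = 2.13e-19, but 0.0568 with an estimated correlation). The counts were 1009 genes for Pristine (474 up, 535 down), 1561 for PEG (527 up, 1034 down) and 1452 for DMPC (269 up, 1183 down). For the Pristine time difference the count was 1860 with quantile normalization, 1611 with normexp background correction (69.6% raised against 47%), 1025 with no filter on dim probes (29.2% raised) and 1324 from the authors' deposited table (68.7% raised). Any 1 replicate number left out gave 483 to 600 genes for the Pristine time difference, 47% to 58.9% of them raised. The PEG time difference gave counts of 2363 with quantile normalization, 1523 with normexp background correction (49.5% raised against 33.8%) and 682 with no filter on dim probes. Any 1 replicate number left out gave 398 to 554 genes for the PEG time difference. The count for the DMPC time difference was 1664 with quantile normalization (38.5% raised against 18.5%), 4330 with normexp background correction (38.3% raised), 720 with no filter on dim probes and 889 with close pairs of arrays averaged. Any 1 replicate number left out gave 807 to 864 genes for the DMPC time difference, 16% to 37.8% of them raised.

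Control cells themselves changed between 24 and 48 h, cell division genes among them. KIF20A, a cytokinesis motor, changed by -2.12 ± 0.15, the mitotic transcription factor gene FOXM1 by -2.62 ± 0.23 and CCNB1 by -1.83 ± 0.13. CYP2A13 rose by 2.46 ± 0.26 and CYP2B6 by 1.15 ± 0.13 (other probe 0.41, adjusted p = 0.752). Of the mitotic list 0 of 23 rose and 23 fell (camera adjusted p = 1.12e-76), while of the replication list 1 of 23 rose and 1 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.458). In all 429 genes changed, 205 up and 224 down. For control cells over time the count was 956 with quantile normalization, 201 with no filter on dim probes (31.3% raised against 47.8%), 285 from the authors' deposited table (33.7% raised), 221 with close pairs of arrays averaged (28.5% raised) and 796 without the arrays nearest to another group (56.9% raised). It was 796 without 24 h control replicate 1 (56.9% raised), 242 without 24 h control replicate 2 (31% raised), 248 without 24 h control replicate 3 (33.9% raised), 241 without 48 h control replicate 1 (29.9% raised) and 272 without 48 h control replicate 2.

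Several lists gave small shifts. With DMPC at 80 µg/cm² and 24 h autophagy genes rose in 4 of 13 (camera adjusted p = 0.0333, but 0.474 with an estimated correlation), with the cargo receptor SQSTM1 at 0.84 ± 0.12. Among iron handling genes with Pristine at 80 µg/cm² and 48 h 1 of 24 rose and 11 fell (camera adjusted p = 0.0083, but 0.411 with an estimated correlation), with TFRC at -1.21 ± 0.16. PPARA targets and fatty acid oxidation genes fell in 15 of 21 (5 rose, camera adjusted p = 5.25e-05, but 0.188 with an estimated correlation) there. Of the phospholipid and lipid droplet list 2 of 15 rose and 9 fell (2 and 10 adjusted over the list alone, camera adjusted p = 0.0077, but 0.472 with an estimated correlation) with DMPC at 80 µg/cm² and 48 h, CIDEC at -1.19 ± 0.11 among them. For ER chaperones with Pristine at 80 µg/cm² and 48 h 1 of 18 rose and 5 fell (camera adjusted p = 0.399), with HSPA5 at -0.79 ± 0.13. Among the blood, macrophage and endothelial markers in the same comparison 1 of 5 rose and 1 fell (camera adjusted p = 0.826).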

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

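Of the tests below, those on the probes that rose together, on all measured snoRNAs, on chlorpromazine alone, on the decline in control cells, on normalization as the whole cause, on dose at 48 h alone, on exchanged times and on the weight that splits carry were chosen only after the result was seen.

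A set of 23 probes, LINC02245, CASC15 and CD86 among them, rose at least 4-fold in at least 4 of the 8 PEG and DMPC comparisons at 1.6 and 16 µg/cm². For PEG and DMPC a particle dose as the cause is argued against by the 19 probes tested at 80 µg/cm², in another slide set. Their median change was -0.48 ± 0.19, against 2.53 over the 23 at 1.6 µg/cm². At 48 h alone it was -0.28 ± 0.15 against 3.50, as at 24 h (-0.80 and -0.36) 2 of 3 controls stood high. Here and below ± is a confidence half-width over genes. Genes are not independent, so it does not measure the spread between arrays or cultures. With Pristine at 48 h the median went up with dose, at -0.22, 0.42 and 1.35, so dose stays open there as well. In 11 of 15 groups the arrays at 1 place on the slide ranged over more than 1, by 4.20 at most. Place alone does not account for that spread, but its part in differences between groups cannot be told apart. Arrays of a close pair differed over these probes by 0.13 in the median of 12 pairs and other pairs of those groups by 1.61 in 24, a ratio of 0.08, so separate preparation of RNA samples within a group is a candidate source. An array of DMPC at 1.6 µg/cm² moved to another slide set stood at 3.97 and its group at 3.34, and a control moved to another place at -0.90 against -1.49. The probes also stood high without a coating, at 3.40 with chlorpromazine (control 0.30), 2.99 on 1 Pristine array at 16 µg/cm² and 2.16 and 1.94 on 2 control arrays of the 80 µg/cm² set, so a coating is not needed for the rise, and a response of some cultures stays open.

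Among 184 snoRNAs 48 were lowered in at least 3 of the 4 PEG and DMPC comparisons at 24 h, with a median of -1.32. These 48 were picked for their fall: all 184 had a median of -0.37, from -0.27 to -0.45 by comparison, and 43 other short RNAs had -0.077 ± 0.26, with 6 to 10 of them lowered in each, a difference of 0.29 ± 0.292. Loss of all 43 by as much as these 48 is argued against. They mix kinds, from SCARNA14 (-2.5) to RPPH1 (0.8), so a smaller or partial loss cannot be told apart. Less RNA of the 33 genes that hold the snoRNAs is argued against (median 0.075 ± 0.088, their snoRNAs -1.33). Transcription was not measured. With chlorpromazine the other short RNAs changed by -1.01 ± 0.60 against -1.02 for snoRNAs. With DMPC at 80 µg/cm² and 48 h it was -1.02 against -1.40. Such loss may explain part of both falls, and faster snoRNA turnover was not tested.

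Mitotic genes stood above control at 80 µg/cm² and 48 h, and the response differed between times, with a median time difference over the list of 2.11 for Pristine, 1.35 for PEG and 1.78 for DMPC. From 24 to 48 h the list changed by -1.55 in control cells. With DMPC it was 0.14 ± 0.14 (1 of 23 rose, 0 fell) and with PEG -0.29 ± 0.11 (0 and 5). So a rise in PEG cells is argued against, and a decline in control cells is a candidate for both. For Pristine (0.39 ± 0.17, 9 and 0) it cannot be told apart from a change in exposed cells. Normalization as the whole cause is argued against, since under another scaling the list stood at least 0.68 ± 0.20 and up to 2.12 above all genes. Its part in the size cannot be told apart, as the lowest ratio to the reported median was 0.53 ± 0.16, with normexp and PEG. Whether the particles kept cells in division or slowed its decline was not tested.

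The response at 80 µg/cm² differed between 48 and 24 h in 1009 genes for Pristine, 1561 for PEG and 1452 for DMPC. Of 100 splits of the arrays 10, 4 and 17 called as many genes in that order, with 7356, 1853 and 5504 in the highest other split. With only the times exchanged within exposed and within control arrays it was 3, 2 and 5 of 100, with 3094, 1892 and 2690. Fewer than 5 of 100 called as many for PEG in both kinds of split and for Pristine with times exchanged. These splits exchange arrays that also differ by exposure or time, and close pairs as separate arrays. They therefore do not exclude chance for the time difference of the response itself. Each of the other splits that called as many carried a net weight on exposed or on 48 h arrays. The structure they point to includes the change with exposure or time itself, and they decide nothing on chance. Splits without such a weight numbered 17, 16 and 14 in the first kind and 45, 38 and 38 with times exchanged, and called at most 0, 2 and 0, and 3, 0 and 320 genes in limma.

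In DMPC at 1.6 µg/cm² and 24 h, which has 4 arrays, replicate 1 lay far from the others in the share of probes well above background (35.8% against 39.0% to 39.6%, a gap of 0.835 of the range) and in the mean of the 23 probes (1.92 against 3.97 to 4.10, a gap of 0.943). Of 31 values tested in groups of 4 arrays 1.6 would pass by chance. The array of that group on a slide without 24 h controls entered no comparison. Against a control array kept out of the choice of genes 94.5% to 95.6% of the genes that changed at least 2-fold in the group moved the same way on it (50% without a change). It lay nearer to replicate 3 (0.0803) than replicate 2 did (0.116), and whether it is a separate preparation was not tested.

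For comparisons of 3 with 3 arrays 10 splits exist, so the share is never under 0.1. In the 20 such comparisons the real split alone (1 of 10) gave its count. The highest other split called 818 genes for DMPC against PEG at 48 h (real 1952), 31 for Pristine at 80 µg/cm² and 24 h (real 5318) and 0 to 2 in limma for the rest. For the 6 comparisons at 48 h with 4 controls 1 of 35 splits, the real one, gave the count, so chance was excluded for arrays taken as separate, with 430 against 4116 for DMPC at 1.6 µg/cm², 426 against 5523 for DMPC at 16 µg/cm², 1072 against 3829 for PEG at 16 µg/cm² and 1 for Pristine at both doses (17 and 130) and PEG at 1.6 µg/cm² (1800). Close pairs of arrays were exchanged as separate arrays in these splits, and with them averaged the counts were 0 (917 at nominal p under 0.05) for Pristine at 1.6 µg/cm², 1 for Pristine at 16 µg/cm² and 1 for PEG at 1.6 µg/cm². For the F tests it was 1 of 100 splits, with 1887 against 4121 genes at 24 h and 4275 against 6040 at 48 h (54 with close pairs averaged). Some of their groups hold close pairs too, so chance is not excluded there either.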

How the results depend on the processing

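The settings with close pairs of arrays averaged and without the arrays nearest to another group were chosen after the results were seen. A count was taken as kept when it lay within 1.5 times the one reported. Counts were kept for 22 of 31 comparisons with quantile normalization, 17 with normexp, 6 with no filter on dim probes, 24 with the authors' deposited table, 6 of 21 with close pairs averaged and 10 of 15 without the arrays nearest to another group. Of 166 gene values named in the report 164 kept direction and side of the threshold with quantile normalization, 163 with normexp, 164 with no filter and 164 with the deposited table. With close pairs averaged 92 of 103 did, and 11 lost their call in the same direction. With 1 array or replicate number left out 988 of 1008 gene values did, 19 lost their call (C16orf82, TELO2, LINC02245, CCNB1 and CYP3A4) and 1 gained one (ASNS). In each of these settings 0 named genes that had passed changed direction. The added array of DMPC at 1.6 µg/cm² and 24 h, set against controls of another slide set, left its count within that range. The gene list tests had 427 calls, and 46 with an estimated correlation.

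With quantile normalization the counts outside that range were 3 for Pristine 1.6 µg/cm² 48 h. It gave 2553 for PEG 80 µg/cm² 24 h. The rest were 4175 for PEG against Pristine 24 h, 1838 for DMPC against Pristine 24 h, 1012 for DMPC against PEG 24 h and 1753 for PEG against Pristine 48 h. It called 1860 for Pristine time difference, 2363 for PEG time difference and 956 for control over time. The cause was not tested.

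Normexp gave 2501 for PEG 1.6 µg/cm² 24 h, 7514 for DMPC 1.6 µg/cm² 24 h, 1268 for PEG 16 µg/cm² 24 h and 10026 for DMPC 16 µg/cm² 24 h. Further counts were 4 for Pristine 1.6 µg/cm² 48 h and 2732 for PEG 1.6 µg/cm² 48 h. There were 9827 for the F test at 24 h and 13622 for the F test at 48 h. It gave 11402 for DMPC 80 µg/cm² 48 h. The rest were 1713 for DMPC against Pristine 24 h, 8006 for DMPC against Pristine 48 h and 3905 for DMPC against PEG 48 h. It called 1611 for Pristine time difference and 4330 for DMPC time difference. The cause was not tested.

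With no filter on dim probes there were 31655 for chlorpromazine, 7 for Pristine 1.6 µg/cm² 24 h, 3901 for PEG 1.6 µg/cm² 24 h, 14519 for DMPC 1.6 µg/cm² 24 h, 372 for Pristine 16 µg/cm² 24 h, 857 for PEG 16 µg/cm² 24 h and 19517 for DMPC 16 µg/cm² 24 h. The rest were 385 for PEG 1.6 µg/cm² 48 h, 1835 for DMPC 1.6 µg/cm² 48 h, 20 for Pristine 16 µg/cm² 48 h, 2019 for PEG 16 µg/cm² 48 h and 3312 for DMPC 16 µg/cm² 48 h. It called 17445 for the F test at 24 h and 14851 for the F test at 48 h. The setting called 643 for PEG 80 µg/cm² 24 h and 1973 for DMPC 80 µg/cm² 24 h. Further counts were 6278 for PEG against Pristine 24 h, 3429 for DMPC against Pristine 24 h, 193 for DMPC against PEG 24 h, 412 for PEG against Pristine 48 h, 1691 for DMPC against Pristine 48 h and 963 for DMPC against PEG 48 h. There were 682 for PEG time difference, 720 for DMPC time difference and 201 for control over time. More genes were tested there, and the dim probes enter both the spread and the adjustment.

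The deposited table, in which background is not subtracted, gave 11 for Pristine 1.6 µg/cm² 24 h and 1101 for PEG 16 µg/cm² 24 h. It called 6 for Pristine 1.6 µg/cm² 48 h and 2595 for DMPC 1.6 µg/cm² 48 h. The setting called 1530 for DMPC against Pristine 24 h and 5452 for DMPC against Pristine 48 h. Further counts were 285 for control over time. The cause was not tested.

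With close pairs averaged there were 4 for Pristine 1.6 µg/cm² 24 h. Further counts were 0 in limma (917 at nominal p under 0.05) for Pristine 1.6 µg/cm² 48 h, 1 for PEG 1.6 µg/cm² 48 h, 185 for DMPC 1.6 µg/cm² 48 h, 1 for Pristine 16 µg/cm² 48 h, 703 for PEG 16 µg/cm² 48 h and 1412 for DMPC 16 µg/cm² 48 h. There were 2209 for the F test at 24 h and 54 for the F test at 48 h. It gave 685 for PEG 80 µg/cm² 24 h and 1755 for DMPC 80 µg/cm² 24 h. The rest were 340 for DMPC against Pristine 24 h and 199 for DMPC against PEG 24 h. It called 889 for DMPC time difference and 221 for control over time. This setting has fewer arrays by construction.

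Without the arrays nearest to another group there were 103 for Pristine 1.6 µg/cm² 24 h. Further counts were 4384 for PEG 1.6 µg/cm² 48 h, 6388 for DMPC 1.6 µg/cm² 48 h and 47 for Pristine 16 µg/cm² 48 h. There were 796 for control over time. The cause was not tested.

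With 1 array, or for F tests and time differences 1 replicate number, left out the counts were 6 to 11 for Pristine 1.6 µg/cm² 24 h, 482 to 682 for PEG 1.6 µg/cm² 24 h, 1676 to 2913 for DMPC 1.6 µg/cm² 24 h, 396 to 667 for Pristine 16 µg/cm² 24 h and 974 to 1899 for PEG 16 µg/cm² 24 h. It called 2 to 10 for Pristine 1.6 µg/cm² 48 h, 687 to 3084 for PEG 1.6 µg/cm² 48 h, 2171 to 5335 for DMPC 1.6 µg/cm² 48 h, 19 to 220 for Pristine 16 µg/cm² 48 h and 2364 to 3444 for PEG 16 µg/cm² 48 h. The setting called 867 to 4338 for the F test at 24 h and 974 to 4035 for the F test at 48 h. Further counts were 768 to 1957 for PEG 80 µg/cm² 24 h. There were 1629 to 2403 for PEG against Pristine 24 h, 392 to 754 for DMPC against Pristine 24 h, 203 to 269 for DMPC against PEG 24 h, 449 to 696 for PEG against Pristine 48 h, 1939 to 3761 for DMPC against Pristine 48 h and 1130 to 2327 for DMPC against PEG 48 h. It gave 483 to 600 for Pristine time difference, 398 to 554 for PEG time difference, 807 to 864 for DMPC time difference and 241 to 796 for control over time. Fewer arrays enter each of these fits.

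The replicate number is the slide, and arrays of 1 slide deviated from their group means with a mean r of 0.0632, 0.102 and 0.114 in the 3 slide sets (lowest -0.093, -0.187 and -0.34), with 26.2%, 53.6% and 56% of pairs over 0.1, so the numbers did not pair every array. What else the arrays of 1 slide share was not tested. With the replicate number as a block the count was 30 for Pristine 1.6 µg/cm² 48 h, and for the F tests 4576 at 24 h and 7044 at 48 h. The other counts stayed within the range above, and 165 of 166 named genes kept their call.

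Signal over background sets a limit for genes that are dim in 1 group: the probes used for CYP8B1 with chlorpromazine and for HSPA6 in the control cells of the set with 80 µg/cm² give only bounds. The median log2 change of mitotic genes with PEG at 80 µg/cm² and 48 h was 0.66 with normexp and its offset against 1.26.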

Other observations

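Small nucleolar RNAs guide the modification of ribosomal RNA. At 48 h, with PEG at 16 µg/cm² 50 of 158 fell and 1 rose (median -0.48), with DMPC at that dose 17 fell and 19 rose (median -0.03), and with Pristine 0 fell and 0 rose in limma (median -0.20), a difference that was not tested itself. Their mean level differed between arrays of a group, at -0.49, -1.09 and -0.50 with DMPC at 16 µg/cm² and -0.57, -0.88, -0.99 and -0.53 in control cells, against -1.20, -1.20 and -1.19 with PEG at that dose. With chlorpromazine 116 of 184 fell and 15 rose (median -1.02). At 80 µg/cm² and 24 h 0 of 152 fell and 0 rose with PEG, 4 fell and 0 rose with DMPC, and 10 fell and 8 rose with Pristine. At 48 h it was 67 and 3 with PEG, 120 and 1 with DMPC and 34 and 6 with Pristine. Other short RNAs fell too, 27 of 43 with chlorpromazine, 8 and 1 of 39 with PEG and DMPC at 16 µg/cm² and 48 h, and 14, 25 and 9 of 35 with PEG, DMPC and Pristine at 80 µg/cm² and 48 h.

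The mean log2 level of the mitotic genes in control cells, relative to the 75th percentile of the array, was 3.12 (n = 3) at 24 h in the set with the lower doses and 0.53 (n = 4) at 48 h in the set with the lower doses. In the set with 80 µg/cm² it was 1.48 at 24 h and -0.16 at 48 h (n = 3 each). These sets lie on separate slides, so cultures and slides cannot be told apart in the first pair of values.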
